A study of Mus musculus with 8 samples.

How the data were processed

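RNA of sorted mouse neural stem and progenitor cells was measured on 1-colour Agilent arrays, 1 array per sample, 8 arrays on 1 slide with 1 scan date. The samples were NFIA-overexpressing and control cells from primary (passage 0, day 6) and secondary (passage 1, day 12) neurospheres, with 2 arrays in each of 4 groups. Per the labels, RNA was isolated with a column kit for small samples, and Cy3-labelled with a low-input kit.

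The deposited scanner files give, per the file headers, the intensity of each spot after background subtraction and detrending within the array by Feature Extraction 10.5.1.1, and flags of other kinds, 0 or 1 per spot, for signal above background, saturation and outliers. The processing notes of the authors name Feature Extraction 10.7.3.1. The value table of the authors holds log2 values, which the values show to be processed signals scaled to the 75th percentile of each array and centred on each probe's median over the 8 arrays (largest absolute probe median 0.000245). Of 62976 spots, 59305 were not controls, and 0 were saturated. Spots well above background made up between 45.38% and 56.44% of an array, and the 75th percentile of the signal lay between 300.8 and 618.

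The columns of the value table were set against the scanner files. A column matched 1 file with a correlation of at least 0.9999, and any other file with at most 0.3385. Only the column of PN_control 2 matched the file attached to its own sample, while 7 columns matched the file of another sample. With arrays assigned as in the value table, 6 of 8 arrays were closest to their own group (mean correlation 0.9687 within and 0.9426 between groups). With arrays assigned as the files are attached, 0 of 8 were (0.931 within and 0.9489 between groups). The analysis follows the value table. That choice was made after this conflict, the Nfia probes and the array correlations had been seen and before any comparison was fitted, so it favours groups whose arrays resemble each other. The file assignment is an alternative throughout. Sample titles and source names also conflict: all 4 control samples have a source name of the NFIA line, and 2 NFIA samples (PN_NFIA 1 and SN_NFIA 2) have a source name of the WT line. Groups follow the titles. By the source names the only WT arrays are 2 titled NFIA, while all 4 arrays titled control count as NFIA. A difference by title is then expected to turn in sign, so such turns are no independent evidence against it. By the value table, passage coincides with the row of the slide and NFIA with its columns, so neither can be told apart from position. If NFIA and control cells are the NFIA and WT lines of the source names, a difference between lines cannot be told apart from NFIA either.

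Signals were taken to log2 and the 75th percentile of the array was subtracted. Probes well above background on both arrays of at least 1 group were kept, and 126 probes were left out by outlier flags. Probe names were taken to gene symbols through the transcript accession on the array, which gave a symbol to 26010 of 55555 probes. The brightest probe of each gene was used, for 13790 genes, of which 3644 had several kept probes.

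Genes were tested with limma 3.58.1 in R 4.3.3, with an adjusted p (Benjamini-Hochberg) under 0.05 over all genes of a comparison. A model of 4 group means gave NFIA against control in primary and in secondary neurospheres, passage in control and in NFIA cells, and the difference of the NFIA effect between passages. A model with additive passage and NFIA terms gave both effects over all 8 arrays. A set of 30 gene lists was written before the data were examined, and tested with camera at a preset correlation of 0.01, adjusted over the 30 lists of a comparison. Named genes are, by a rule also fixed then, the 10 genes that rose and the 10 that fell most among those past the test whose groups do not overlap (5 each way for passage in control cells, passage in NFIA cells and the difference of effects), the 4 members of each list with the smallest p, and a fixed set of markers. Some genes that meet the rule are not reported here. A gene not well above background on any array of the lower side is given as at least a fold, with no error: the mean of the higher side was set against the lower side with each of its arrays raised to the lowest signal well above background on that array. This bound allows for dim signal and not for the spread between arrays. It can exceed the lower confidence limit of the estimate, as for Hic1 in primary neurospheres (5.13 against 3.84 in log2). For Cyp1b1 the raising changed nothing, so its estimate is given. The alternatives to the choices above were fixed then too, apart from the file assignment, the replicate block within each passage, the crossed block and the inclusion of transcripts without a symbol, which were chosen after seeing the data.

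In simulated arrays with 200 of 13790 genes changed, the test over both passages called 32.8% of genes changed by 1 (log2), 92.5% of those changed by 2 and 100% of those changed by 4 for NFIA, and 32.8%, 85.1% and 97% for passage. For NFIA the shares were 2.99%, 67.2% and 98.5% in primary and 2.99%, 55.2% and 98.5% in secondary neurospheres. For passage they were 2.99%, 64.2% and 97% in control cells and 1.49%, 68.7% and 95.5% in NFIA cells, and for the difference of effects 0%, 17.9% and 87.9%. The simulated arrays varied independently of each other, without any pairing, so the shares in the measured arrays may differ.

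Equally numbered arrays were checked for pairing. Their deviations from the group mean correlated across 11669 genes with r = 0.53 between PN_control and PN_NFIA and 0.53 between SN_control and SN_NFIA, and with -0.28, -0.085, -0.21 and 0.014 between passages. With pairs within a passage as a replicate block, 355 genes were called for NFIA over both passages. Planned background correction used the median signal with the median local background, as the files hold no mean signal. The row of the slide could not be fitted as a block.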

Results

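Gene expression was measured in neural stem and progenitor cells grown as neurospheres from mouse embryonic stem cells. Each culture mixed cells that overexpress the transcription factor NFIA, a regulator of the start of astrocyte formation, with control cells, and the 2 cell types were parted by cell sorting before RNA was taken. The samples form 4 groups of 2 arrays: control cells of primary neurospheres (PN_control, passage 0, day 6), NFIA cells of primary neurospheres (PN_NFIA), control cells of secondary neurospheres (SN_control, passage 1, day 12) and NFIA cells of secondary neurospheres (SN_NFIA). Between 45.4% and 56.4% of the non-control spots of an array were well above background, and 13790 genes entered the tests. Values are log2 differences ± SE from limma, and adjusted p is over all genes tested unless stated. The number of arrays limits the precision. For 7 of the 8 samples the attached scanner file and the authors' value table hold different arrays, so every value below follows the value table, and counts under the other assignment stand beside the counts of each comparison.

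Nfia, the overexpressed gene, was higher in the NFIA arrays in both passages, but its brighter probe did not pass the test over all genes. That probe stood at -1.30 and -0.29 in the PN_control arrays, -0.23 and 0.94 in the PN_NFIA arrays, 1.01 and 0.63 in the SN_control arrays, and 1.70 and 1.63 in the SN_NFIA arrays. The difference was 1.00 ± 0.32 over both passages (4 NFIA against 4 control arrays, adjusted p = 0.171), with 1.15 ± 0.48 in primary and 0.85 ± 0.48 in secondary neurospheres. With the pairs of equally numbered arrays as a replicate block within each passage, the adjusted p over both passages was 0.0458, in a range of 0.0458 to 1 over the alternatives to the fit. The second Nfia probe differed by 1.94, with 2.05 in primary and 1.83 in secondary neurospheres. Whether either probe lies within the introduced sequence is not known. With arrays taken from the attached scanner files the differences were 0.16 and 0.11. With groups from the source names the difference of the brighter probe turned negative, as a difference by title is expected to do there.

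**Figure D1:**
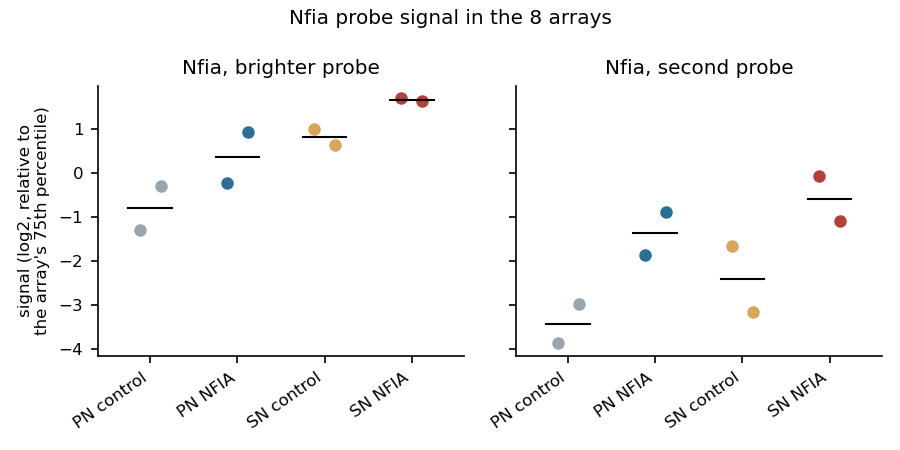
Signal of both Nfia probes in each of the 8 arrays (log2, relative to the array's 75th percentile), by group; points are arrays and lines are group means. The SN_NFIA arrays have the highest values of the brighter probe, 1.70 and 1.63.

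The comparison of NFIA with control cells over both passages asks which genes go with NFIA overexpression whatever the passage. Ecrg4, a gene for a secreted peptide of choroid plexus, was higher in NFIA cells by 6.28 ± 0.82, and Myh8, a myosin heavy chain gene, by 5.68 ± 0.38 (4 arrays a side). Wif1, which encodes a secreted Wnt inhibitor, rose by 4.16 ± 0.54, the retinol carrier gene Rbp4 by 3.97 ± 0.53, the laminin receptor gene Itga7 by 3.91 ± 0.54, and Gas6, which encodes a ligand of TAM receptor kinases, by 3.87 ± 0.52. Serpinb5 was at least 7.91-fold and the potassium channel gene Kcnt1 at least 12.3-fold higher, as neither was well above background in any control array. The Y-linked genes Ddx3y, Eif2s3y and Uty had the largest decreases and fell by 3.34 ± 0.58, 3.02 ± 0.43 and 2.95 ± 0.54. The proneural gene St18 fell by 2.10 ± 0.31. In all, 241 genes rose and 26 fell at an adjusted p under 0.05 in limma, with 2443 genes at an unadjusted p under 0.05.

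Genes of astrocytes moved up as a set. Of 31 measured, 1 rose over all genes and 12 rose when adjusted over the list alone, and 29 had a positive difference (median 1.44, camera adjusted p = 6.47e-10; adjusted p = 0.354 with an estimated correlation). With groups from the source names the list pointed down (camera adjusted p = 3.27e-09). Sparcl1 rose by 3.08 ± 0.51 (adjusted p = 0.0302), while Aldoc (2.85 ± 0.57) and Cd44 (1.87 ± 0.38) did not pass over all genes. The probe used for Gfap, the intermediate filament gene of mature astrocytes, was well above background on 2 NFIA and 0 control arrays (adjusted p = 0.245). Slc1a3, a glutamate transporter gene of astrocytes and radial glia, differed by 1.44 ± 0.35 (adjusted p = 0.0924). All 4 NFI family genes rose when adjusted over the list alone and 0 over all genes, with Nfix at 2.04 ± 0.48 (camera adjusted p = 0.00102; adjusted p = 0.354 with an estimated correlation). Of the 4 early glial genes linked to SOX9 and NFIA, Zcchc24 (1.64 ± 0.34) rose when adjusted over the list alone and 0 rose over all genes (camera adjusted p = 0.00316; adjusted p = 0.266 with an estimated correlation).

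Genes of neurogenesis moved down. Of 22 proneural and neurogenic progenitor genes measured, St18 and Dll3 (-1.36 ± 0.24) fell over all genes and 7 fell when adjusted over the list alone (median -0.87, camera adjusted p = 7.14e-06; adjusted p = 0.354 with an estimated correlation). Of 32 neuronal genes, 0 fell over all genes and 2 when adjusted over the list alone, with Slc17a6, the vesicular glutamate transporter gene, at -1.55 ± 0.35 (median -1.06, camera adjusted p = 7.16e-06; adjusted p = 0.409 with an estimated correlation). Among 27 cell cycle genes the difference was negative for 26, with 0 falling over all genes and 2 when adjusted over the list alone (median -0.48, camera adjusted p = 2.62e-07; adjusted p = 0.409 with an estimated correlation). Ccna2, the cyclin A2 gene, differed by -0.80 ± 0.17. The 11 early progenitor genes, among them the let-7 regulator Lin28b (-1.62 ± 0.44), had a median of -0.67, with 0 past the test over all genes and 0 when adjusted over the list alone (camera adjusted p = 0.0238; adjusted p = 0.434 with an estimated correlation).

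Signalling genes that moved up included the Notch effector gene Hes1 (1.54 ± 0.25, adjusted p = 0.0295) and Cebpd, a target gene of STAT3 (1.66 ± 0.31, adjusted p = 0.042). The BMP effector gene Smad9 was at least 1.56-fold (adjusted p = 0.00397) and the interferon-induced gene Rsad2 at least 3.33-fold higher (adjusted p = 0.0211), since no control array had either well above background. Each was the sole member of its list past the test over all genes. Adjusted over the list alone, 3 of 13 Notch pathway genes, 1 of 14 BMP and ID genes, 4 of 7 interferon response genes, 5 of 13 JAK-STAT and gp130 genes and 6 of 10 immediate early genes rose. Their camera adjusted p was 0.00245, 0.0148, 0.00088, 0.00013 and 0.00013 in that order. With an estimated correlation the adjusted p was 0.354 for the Notch pathway, 0.266 for BMP and interferon genes, 0.198 for JAK-STAT and 0.409 for immediate early genes. Mesodermal and mesenchymal genes moved up too, from a rise in primary neurospheres (median 1.5, against -0.32 with a camera adjusted p of 0.397 in secondary ones), with Prrx1 at 1.88 ± 0.24 and Acta2 at 1.69 ± 0.31 as the 2 of 17 that rose, over all genes and adjusted over the list alone (camera adjusted p = 0.00223; adjusted p = 0.518 with an estimated correlation). Of 14 extracellular matrix and adhesion genes 12 were positive and 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.00088; adjusted p = 0.266 with an estimated correlation). The other 16 lists had a camera adjusted p over 0.05. With the replicate block within each passage 2 of these, forebrain patterning genes (median -0.59) and posterior HOX genes (median 0.54), had a camera adjusted p of 0.0258 and 0.012 (adjusted p = 0.624 and 0.597 with an estimated correlation). Klf4 (1.33 ± 0.22) rose alone of 20 pluripotency genes, a list whose median (-0.39) and mean (-0.11) were negative while camera pointed up (camera adjusted p = 0.822). The same held for 10 endoderm genes (median -0.53, mean -0.01, camera adjusted p = 0.65), and for 7 cell cycle inhibitors the median was -0.18 but the mean 0.45 (camera adjusted p = 0.862). Medians of blood and microglia, ependymal and choroid, midbrain and hindbrain, ventral neural tube, dorsal neural tube and DNA methylation genes were 0.24, 0.19, 0.1, 0.06, 0.13 and -0.13, with camera adjusted p of 0.281, 0.438, 0.438, 0.969, 0.65 and 0.683. No camera call of any comparison held with an estimated correlation.

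For the comparison over both passages the attached scanner files gave 0 called genes in limma and 301 at an unadjusted p under 0.05. Leaving out the 2 arrays titled NFIA whose source name says WT (PN_NFIA 1 and SN_NFIA 2) gave 67 called genes, and leaving out SN_NFIA 1 alone gave 33, PN_NFIA 2 62, SN_control 1 91, PN_control 1 100, PN_control 2 110 and SN_NFIA 2 131. The source names, by which 2 arrays are WT and 6 NFIA, turned 9 of the 14 called lists to a call in the other direction and kept 0, astrocyte, neuronal, proneural and cell cycle genes among those turned. Both of those WT arrays are titled NFIA, so a difference by title is expected to turn in sign there. The turn is no independent evidence against it. The attached files turned 0 and kept 1.

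In primary neurospheres the comparison asks which genes differ between NFIA and control cells at passage 0. If the 2 cell types are different lines, a difference between lines cannot be told apart from NFIA. Tnc, the tenascin C gene of the astrocyte list, was at least 22.3-fold higher and the transcriptional repressor gene Hic1 at least 35-fold. The aldehyde dehydrogenase gene Aldh3b1 was at least 13.3-fold higher, as none of these was well above background in the PN_control arrays. The cytochrome gene Cyp1b1, also not well above background there, rose by 5.26 ± 0.36, and its bound of 38.4-fold equals this estimate. The bound for Tnc is that of its brighter probe (4.48 in log2), while its other probe differed by 3.83. Myh8 rose by 5.64 ± 0.56 and the collagen gene Col6a1 by 2.94 ± 0.34 (2 arrays a side). Cdkn2b, a cell cycle inhibitor gene, was at least 6.64-fold higher by its brighter probe, while its other probe differed by -0.28. In all, 43 genes rose and 0 fell at an adjusted p under 0.05 in limma, with 1318 at an unadjusted p under 0.05.

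Mesodermal and mesenchymal genes had the smallest camera p of the 30 lists in primary neurospheres. All 17 were positive, 0 rose over all genes and 6 when adjusted over the list alone, with Pdgfrb at 1.99 ± 0.35 and Col1a1 at 2.64 ± 0.51 (median 1.5, camera adjusted p = 4.27e-11; adjusted p = 0.2 with an estimated correlation). Of 14 extracellular matrix and adhesion genes Col6a1 rose over all genes and 7 when adjusted over the list alone (median 1.12, camera adjusted p = 6.96e-07; adjusted p = 0.2 with an estimated correlation). Pluripotency genes were positive for 19 of 20, with 0 past the test over all genes and 2 adjusted over the list alone, among them Fgf4 at 1.48 ± 0.31 (median 0.84, camera adjusted p = 3.22e-06; adjusted p = 0.557 with an estimated correlation). Of 10 endoderm genes 0 rose over all genes and 3 when adjusted over the list alone, with Sox7 at least 1.59-fold higher (median 1.16, camera adjusted p = 0.000231; adjusted p = 0.41 with an estimated correlation). The array PN_NFIA 1 stood apart in this group, with the yolk sac and liver gene Afp at -1.27 against -4.61 in PN_NFIA 2 and Gata4 at -1.45 against -4.68, genes chosen after their values were seen.

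Neural lists moved in primary neurospheres as well. Of 31 astrocyte genes Tnc rose over all genes and 3 when adjusted over the list alone (median 0.93, camera adjusted p = 2.77e-05; adjusted p = 0.591 with an estimated correlation). The NFI family had 2 members rising when adjusted over the list alone and 0 over all genes (median 1.31, camera adjusted p = 0.000547; adjusted p = 0.41 with an estimated correlation). Of 22 proneural genes 0 fell by either adjustment, over all genes or adjusted over the list alone, with the Notch ligand gene Dll1 at -1.1 ± 0.31 (median -0.85, camera adjusted p = 6.63e-05; adjusted p = 0.589 with an estimated correlation). All 27 cell cycle genes were negative and 0 fell over all genes or adjusted over the list alone (median -0.39, camera adjusted p = 4.85e-05; adjusted p = 0.591 with an estimated correlation). Of 32 neuronal genes 27 were negative, with 0 passing over all genes or adjusted over the list alone (median -0.57, camera adjusted p = 0.00534; adjusted p = 0.622 with an estimated correlation). Interferon response genes had a median of 1.56 with 3 of 7 rising when adjusted over the list alone and 0 over all genes (camera adjusted p = 4.85e-05; adjusted p = 0.292 with an estimated correlation). Early glial, Notch pathway, JAK-STAT and immediate early genes also moved up, with medians of 1.1, 0.30, 0.69 and 1.15 and camera adjusted p of 0.0164, 0.0188, 0.0012 and 0.0042. Over all genes 0 of their members passed, and adjusted over the list alone 1, 3, 0 and 0 rose. Their adjusted p was 0.314, 0.591, 0.2 and 0.591 with an estimated correlation. Neural stem cell and radial glia genes (median -0.31) had a camera adjusted p of 0.0521, and of 0.022 with the replicate block within each passage (adjusted p = 0.588 with an estimated correlation).

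In primary neurospheres the attached scanner files gave 0 called genes in limma with 142 at an unadjusted p under 0.05. Normexp background correction gave 8, quantile normalization 19, the replicate block within each passage 70, and the 2 groups fitted alone 138. Without the filter on dim probes, and under the source names, 0 genes were called. Leaving out PN_control 1, PN_control 2 or PN_NFIA 1 left 0 called genes and leaving out PN_NFIA 2 left 1, while leaving out either SN_control array gave 85 and either SN_NFIA array 12. Of the 14 called lists the source names turned 7 to a call in the other direction and kept 0, and the attached files turned 0 and kept 4.

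In secondary neurospheres the comparison asks the same after passage, and genes changed in both directions. Serpinb5 was at least 20.4-fold higher, the surfactant protein gene Sftpc at least 13.9-fold and the transporter gene Abca8a at least 5.39-fold, as none was well above background in the SN_control arrays. Myh8 rose by 5.72 ± 0.56, Rbp4 by 4.80 ± 0.66 and Scube2, which encodes a secreted carrier of Hedgehog ligands, by 4.06 ± 0.38 (2 arrays a side). Mogat2, a gene of triglyceride synthesis, was at least 20.6-fold lower in NFIA cells and Ddx3y at least 19.3-fold lower. Uty was at least 4.28-fold and the claudin gene Cldn6 at least 4.24-fold lower, while the desmosome gene Dsg1c fell by 4.22 ± 0.50. Vmn1r197 fell by 4.73 ± 0.50. Olfr1254, Dcstamp, Olfr487 and Cd160 were at least 4.75-fold, 4.68-fold, 4.4-fold and 3.48-fold lower. Olfr1254, Dcstamp, Olfr487 and Cd160 lay between -3.1 and -1.25 in SN_control arrays. In all primary and SN_NFIA arrays they lay between -6.77 and -6.05. Their decreases thus go with a level in SN_control arrays above that of every other group. In all, 66 genes rose and 59 fell at an adjusted p under 0.05 in limma, with 2071 at an unadjusted p under 0.05. Normexp background correction turned the split to 134 up and 50 down.

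Astrocyte genes moved up in secondary neurospheres too, but down under the attached scanner files (camera adjusted p = 0.0097) and the source names (camera adjusted p = 2.75e-11). Of 31 measured, Acsbg1 (1.79 ± 0.26, adjusted p = 0.0408) rose over all genes and 12 rose when adjusted over the list alone (median 1.84, camera adjusted p = 1.72e-09; adjusted p = 0.54 with an estimated correlation). Dio2, which encodes the enzyme that activates thyroid hormone, was at least 1.2-fold higher (adjusted p = 0.058). The Gfap probe used was well above background on both SN_NFIA arrays and on 0 SN_control arrays (adjusted p = 0.207). Aqp4, the astrocyte water channel gene, differed by 2.52 ± 1.77 (adjusted p = 0.571), with 1 of 2 SN_control arrays well above background. Id3, a BMP target gene, rose by 2.15 ± 0.24 and Smad9 was at least 1.89-fold higher, with 3 of 14 BMP and ID genes rising when adjusted over the list alone (camera adjusted p = 0.0135; adjusted p = 0.54 with an estimated correlation). JAK-STAT, immediate early, Notch pathway, early glial and NFI family genes moved up with medians of 0.73, 1.29, 0.81, 1.05 and 0.78. Over all genes 0 members of these passed, and adjusted over the list alone 2, 0, 1, 0 and 0 rose. Their camera adjusted p was 0.00233, 0.00191, 0.0127, 0.0135 and 0.0479, and for each the adjusted p was 0.54 with an estimated correlation.

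Neuronal and pluripotency genes stood lower in SN_NFIA cells, but higher under the attached scanner files (camera adjusted p = 0.00477 and 0.0097), as neuronal genes did under the source names (camera adjusted p = 1.48e-05). Of 32 neuronal genes Syt4 (at least 2.68-fold lower) fell over all genes and 5 fell when adjusted over the list alone (median -1.33, camera adjusted p = 3.76e-06; adjusted p = 0.54 with an estimated correlation). Of 22 proneural genes Neurod2 (-2.76 ± 0.39) and St18 (-2.61 ± 0.39) fell over all genes and 5 when adjusted over the list alone (median -0.94, camera adjusted p = 8.51e-05; adjusted p = 0.54 with an estimated correlation). Of 20 pluripotency genes Fgf4 (-2.30 ± 0.31) and Zscan10 (-2.77 ± 0.39) fell over all genes and 9 fell and 1 rose when adjusted over the list alone (median -1.35, camera adjusted p = 0.000596; adjusted p = 0.54 with an estimated correlation). Pou5f1 stood at -2.45 ± 0.54 (adjusted p = 0.0904) and Klf4 at 1.65 ± 0.28 (adjusted p = 0.0541). Of 10 endoderm genes Cdh1, the E-cadherin gene, fell by 2.22 ± 0.33 and Sox7 was at least 2.25-fold higher, and adjusted over the list alone 5 fell and 2 rose (median -1.47, camera adjusted p = 0.072). Early progenitor genes had a median of -1.28 with 3 of 11 falling when adjusted over the list alone and 0 over all genes (Lin28a -3.36 ± 0.65, camera adjusted p = 0.00191; adjusted p = 0.54 with an estimated correlation). Cell cycle genes had a median of -0.62, with 0 of 27 past the test over all genes or adjusted over the list alone (camera adjusted p = 1.67e-05; adjusted p = 0.54 with an estimated correlation). With the replicate block within each passage neural crest (median -0.80), forebrain patterning (median -0.89) and posterior HOX genes (median 0.84) also passed, at camera adjusted p of 0.0445, 0.0315 and 0.00119 (adjusted p = 0.598, 0.658 and 0.417 with an estimated correlation).

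The array SN_control 2 stood apart in oligodendrocyte lineage genes: Mag was at 5.67 against -3.91 in SN_control 1 and Gpr17 at 7.45 against 0.54, genes chosen after their values were seen. SN_NFIA 2 had Gpr17 at 5.51. In this comparison Mbp, the myelin basic protein gene, fell by 2.06 ± 0.31 in NFIA cells, alone of 18 oligodendrocyte lineage genes over all genes and adjusted over the list alone (median -0.25, camera adjusted p = 0.69).

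In secondary neurospheres the attached scanner files gave 0 called genes in limma with 514 at an unadjusted p under 0.05, the replicate block within each passage gave 644, and the 2 groups fitted alone gave 0. Leaving out SN_control 2 gave 457 called genes, SN_control 1 56, either PN_NFIA array 72, either PN_control array 10, SN_NFIA 1 21 and SN_NFIA 2 6. Of the 12 called lists the source names turned 6 to a call in the other direction and the attached files 3, and both kept 0.

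**Figure D2:**
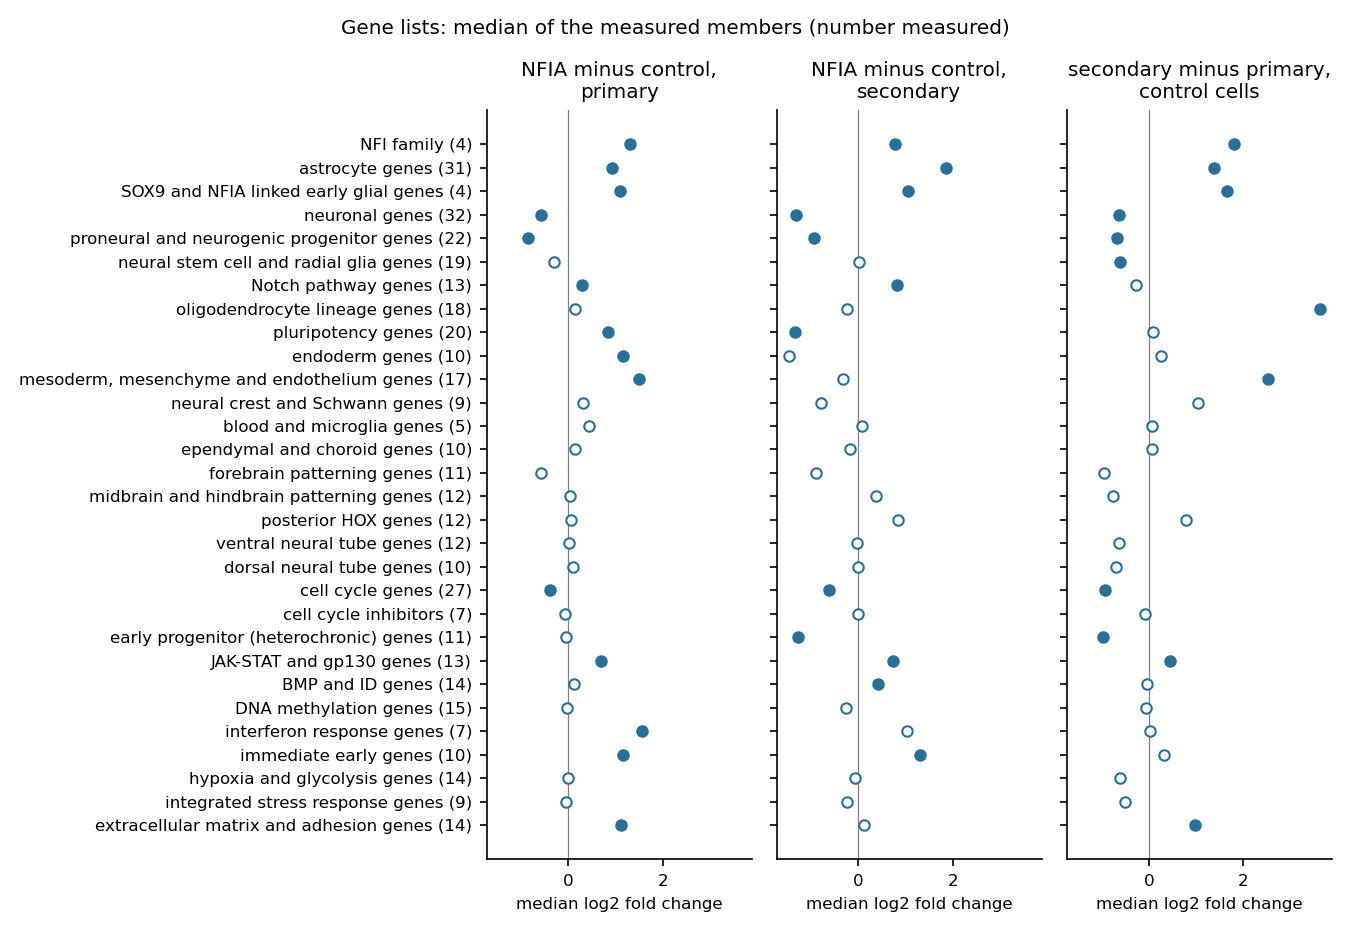
Median log2 fold change of the measured members of 30 gene lists in 3 comparisons; the number measured stands after each name, and filled points have a camera adjusted p under 0.05 at the preset correlation. Astrocyte genes lie at 0.93, 1.84 and 1.38, and pluripotency genes at 0.84, -1.35 and 0.10.

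Whether the NFIA effect differs between passages was tested as an interaction. No gene passed in limma: 0 were called, with 919 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0705. Fgf4 had the smallest p among pluripotency genes, with an effect lower in secondary neurospheres by -3.78 ± 0.44 (adjusted p = 0.0794). As sets, 7 lists had a more negative and 2 a more positive NFIA effect in secondary neurospheres. Some of these calls were lost on leaving out PN_control 2, PN_NFIA 1 or any single secondary array. Pluripotency genes differed by a median of -1.73, with 10 of 20 passing downward when adjusted over the list alone (camera adjusted p = 4.92e-11; adjusted p = 0.517 with an estimated correlation). Mesodermal and mesenchymal genes differed by -1.64, with 5 of 17 lower when adjusted over the list alone, among them Pdgfrb at -2.71 ± 0.49 (camera adjusted p = 2.01e-09; adjusted p = 0.517 with an estimated correlation). Endoderm genes differed by -2.33, with 5 of 10 lower when adjusted over the list alone and Cdh1 at -3.44 ± 0.47 (camera adjusted p = 1.49e-05; adjusted p = 0.517 with an estimated correlation). The endoderm list holds Krt8, Krt18 and Cdh1, which are also among the epithelial genes looked at below. With the replicate block within each passage oligodendrocyte lineage genes (median -1.32) and posterior HOX genes (median 0.56) passed too, at camera adjusted p of 0.0064 and 0.00642 (adjusted p = 0.708 and 0.584 with an estimated correlation). The attached scanner files gave 0 called genes with 255 at an unadjusted p under 0.05, and leaving out SN_control 1 gave 29 and SN_control 2 1. Of the 9 called lists the attached files turned 2 to a call in the other direction, astrocyte and neuronal genes, and the source names 8, and both kept 0.

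The comparison of secondary with primary neurospheres over both cell types asks what changes with passage whatever the NFIA level. Among the genes named here, several glial genes were higher and several neurogenic genes lower in secondary neurospheres. Nfix, a relative of Nfia, was higher by 4.36 ± 0.48, the oligodendrocyte lineage factor gene Olig1 by 4.16 ± 0.70, the calcium-binding protein gene S100a4 by 4.43 ± 0.75 and the myelin glycoprotein gene Omg by 5.73 ± 1.32 (4 arrays a side). Tbr1, a transcription factor gene of newborn cortical glutamatergic neurons, was lower by -4.78 ± 0.40, the neurogenic factor gene Nhlh2 by -4.91 ± 0.63, and the ventral forebrain factor gene Gsx2 by -4.59 ± 0.74. The Wnt agonist gene Rspo2 was at least 10.2-fold lower, as it was not well above background in any secondary array. In all, 461 genes rose and 518 fell at an adjusted p under 0.05 in limma. At an unadjusted p under 0.05 there were 3626 genes. Equally numbered arrays of a passage deviated together (r = 0.53), so the 4 arrays a side are not independent. The fit takes them as independent, and pairs cannot be fitted as a block for passage. These SEs and counts may therefore be too favourable. With the 75th percentile taken over probes above background on all arrays, the split was 604 up and 385 down.

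All 4 NFI family genes rose between passages, over all genes and adjusted over the list alone, with Nfia at 1.46 ± 0.32 and Nfib at 1.65 ± 0.38 (camera adjusted p = 8.59e-05; adjusted p = 0.288 with an estimated correlation). Of 31 astrocyte genes 10 rose over all genes and 22 when adjusted over the list alone, among them Gfap (at least 2.48-fold, adjusted p = 0.0493), Aldh1l1 (2.56 ± 0.57) and Slc1a3 (1.52 ± 0.35) (median 1.80, camera adjusted p = 2.13e-12; adjusted p = 0.293 with an estimated correlation). The Gfap probe was well above background on 2 secondary arrays, both SN_NFIA, and on 0 SN_control arrays. In control cells alone its adjusted p was 0.423 in limma, so 2.48-fold is no bound for them. S100b stood at 5.83 ± 1.82 (adjusted p = 0.0927). Of 18 oligodendrocyte lineage genes 4 rose over all genes and 11 when adjusted over the list alone, with Pdgfra at 3.12 ± 0.71 and Sox8 at 3.76 ± 0.76 (median 3.33, camera adjusted p = 3.72e-07; adjusted p = 0.377 with an estimated correlation). The median of this list was 3.28 in SN_control 2 against 0.10 in SN_control 1, and 1.71 in SN_NFIA 2 against 0.05 in SN_NFIA 1. Of 27 cell cycle genes 17 fell over all genes and 23 when adjusted over the list alone, with the proliferation marker gene Mki67 at -0.90 ± 0.15 and Ccnd1 at -1.22 ± 0.21 (median -0.98, camera adjusted p = 2.13e-12; adjusted p = 0.293 with an estimated correlation).

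Of 32 neuronal genes 7 fell over all genes and 12 when adjusted over the list alone, with Slc17a6 at -3.61 ± 0.35 (median -1.15, camera adjusted p = 0.000105; adjusted p = 0.44 with an estimated correlation). Of 22 proneural genes 3 fell over all genes and 8 when adjusted over the list alone, with Eomes at -2.68 ± 0.34 and Neurod1 at least 4.61-fold lower (median -0.94, camera adjusted p = 0.000106; adjusted p = 0.377 with an estimated correlation). Neural stem cell genes had 3 of 19 falling over all genes and 5 when adjusted over the list alone, among them Pax6 at -2.15 ± 0.30, whereas Sox2 stood at -0.07 ± 0.21 and Nes at -0.79 ± 0.42, neither past the test (camera adjusted p = 0.0385; adjusted p = 0.578 with an estimated correlation). Of 11 early progenitor genes 3 fell over all genes and 8 when adjusted over the list alone, with Igf2bp2 at -1.34 ± 0.18 and Lin28b at -2.17 ± 0.44 (median -1.34, camera adjusted p = 8.59e-05; adjusted p = 0.288 with an estimated correlation). Extracellular matrix genes had 5 of 14 rising over all genes and 5 when adjusted over the list alone, with Lama2 at 2.67 ± 0.47, and mesodermal genes had 4 of 17 rising over all genes and 9 when adjusted over the list alone, with Dcn at 3.15 ± 0.43. Their camera adjusted p was 0.000286 and 0.000725, and their adjusted p was 0.288 and 0.44 with an estimated correlation. Early glial, JAK-STAT, BMP and posterior HOX genes moved up with medians of 1.68, 0.74, 0.28 and 1.51 and camera adjusted p of 0.00192, 0.00114, 0.0387 and 0.0166. Their adjusted p was 0.277, 0.277, 0.293 and 0.578 with an estimated correlation. Forebrain patterning, hypoxia, integrated stress response and pluripotency genes moved down with medians of -1.43, -0.66, -0.55 and -0.86 and camera adjusted p of 0.0166, 0.013, 0.0245 and 0.0423. Their adjusted p was 0.572, 0.578, 0.293 and 0.642 with an estimated correlation. Pluripotency genes fell in NFIA cells (median -2.12), while in control cells their median was 0.10 (camera adjusted p = 0.34).

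For passage over both cell types the attached scanner files gave 0 called genes in limma with 78 at an unadjusted p under 0.05, and passage coincided with the row of the slide. Leaving out the 2 arrays of conflicting names gave 0, and leaving out 1 array gave 51 without PN_NFIA 1, 118 without PN_control 1, 148 without PN_control 2, 229 without SN_NFIA 1, 269 without PN_NFIA 2, 283 without SN_NFIA 2 and 1650 without SN_control 1. Of the 18 called lists the attached files kept 2 and the source names 17, with 0 turned.

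**Figure D3:**
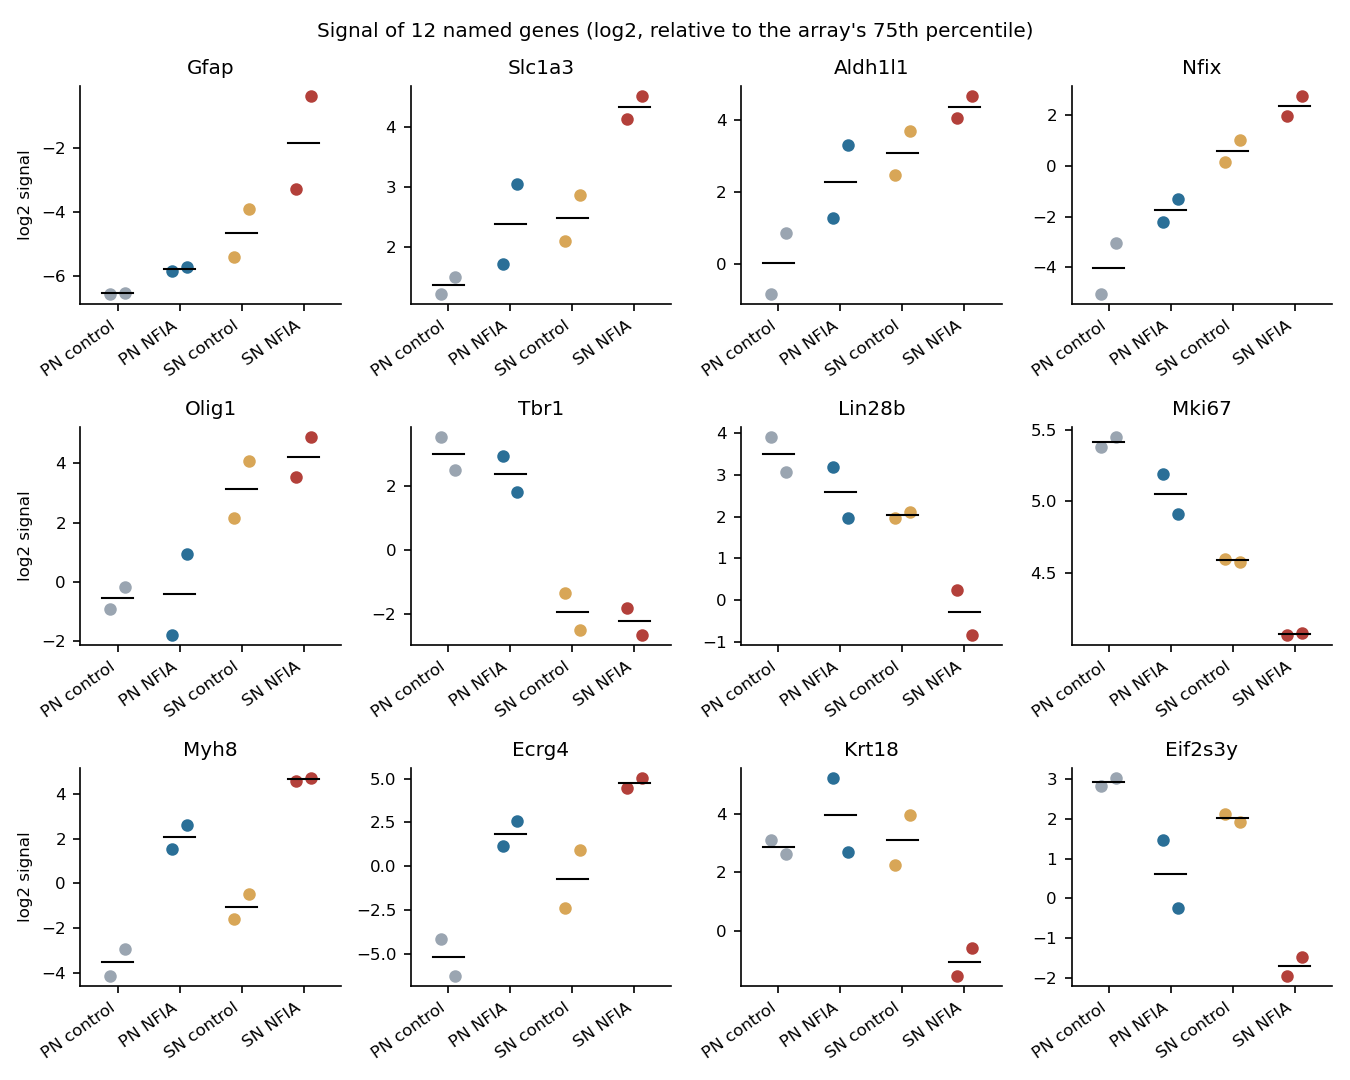
Signal of 12 named genes in each of the 8 arrays (log2, relative to the array's 75th percentile), by group; points are arrays and lines are group means. Mki67 was higher by 0.90 in primary arrays, while Eif2s3y was lower by 3.02 in NFIA arrays.

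In control cells alone the passage comparison asks how cells without added NFIA change. Cyp1b1 was higher in secondary neurospheres by 5.82 ± 0.36, and its bound of 56.4-fold equals this estimate. The matricellular gene Ccn4 was at least 21.9-fold higher by its brighter probe (4.45 in log2), while its other probe differed by 3.57. Col1a1 rose by 5.46 ± 0.51 and S100a4 by 5.77 ± 0.86 (2 arrays a side). Tbr1 fell by 4.94 ± 0.60 and Slc17a6 by 3.21 ± 0.48, while Rspo2 was at least 12.2-fold lower. In all, 96 genes rose and 15 fell at an adjusted p under 0.05 in limma, with 1848 at an unadjusted p under 0.05. Quantile normalization gave 79 up and 29 down, and normexp 74 up and 29 down. The median of all genes lay at -0.12 and moved to 0.04 when the percentile was taken over probes above background on all arrays.

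Mesodermal and mesenchymal genes moved up in control cells, with 4 of 17 rising over all genes and 9 when adjusted over the list alone, among them Pdgfrb at 3.12 ± 0.35 and Lum at 3.63 ± 0.42 (median 2.53, camera adjusted p = 7.02e-10; adjusted p = 0.275 with an estimated correlation). Of 31 astrocyte genes Tnc (at least 19.3-fold) rose over all genes and 7 when adjusted over the list alone (median 1.38, camera adjusted p = 2.25e-09; adjusted p = 0.455 with an estimated correlation). Oligodendrocyte lineage genes had a median of 3.62 with 0 of 18 past the test over all genes and 7 adjusted over the list alone (camera adjusted p = 1.57e-08; adjusted p = 0.455 with an estimated correlation). All 27 cell cycle genes were negative, with 0 falling over all genes and 18 when adjusted over the list alone (median -0.93, camera adjusted p = 9.27e-11; adjusted p = 0.455 with an estimated correlation). Nfix rose by 4.62 ± 0.70 and all 4 NFI family genes rose when adjusted over the list alone (camera adjusted p = 1.26e-05; adjusted p = 0.292 with an estimated correlation). Pax6 fell by 2.73 ± 0.32, alone among 19 neural stem cell genes over all genes and adjusted over the list alone (camera adjusted p = 0.00245; adjusted p = 0.455 with an estimated correlation). In all, 7 lists moved up and 5 down in control cells by camera. Hes5, a Notch effector gene of neural progenitors, stood at -1.44 ± 0.37 (adjusted p = 0.171).

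In control cells the attached scanner files gave 0 called genes in limma with 355 at an unadjusted p under 0.05, and the 2 groups fitted alone gave 0. Leaving out SN_control 1 gave 434, SN_control 2 51, PN_control 1 8, PN_control 2 10 and either PN_NFIA array 64. Of the 12 called lists the attached files kept 0 and the source names 9, with 0 turned.

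In NFIA cells the passage comparison gave more genes that fell than rose. Krt18, a keratin gene of simple epithelia, fell by 5.04 ± 0.90, Nhlh2 by 5.67 ± 0.84 and the neuropeptide gene Cartpt by 4.88 ± 0.83, while Mogat2 was at least 19.0-fold lower (2 arrays a side). The glutamate receptor gene Grm5 rose by 4.55 ± 0.46 by its brightest probe, with the other probes between 0.17 and 4.10, and the potassium channel gene Kcnj16 was at least 11.6-fold and Sftpc at least 24.0-fold higher, neither being well above background in PN_NFIA arrays. In all, 75 genes rose and 186 fell at an adjusted p under 0.05 in limma, with 2935 at an unadjusted p under 0.05. Normexp gave 122 up and 146 down. Of 20 pluripotency genes 6 fell over all genes and 13 fell and 1 rose when adjusted over the list alone, with Esrrb at -2.52 ± 0.32 and Utf1 at -1.99 ± 0.28 (median -2.12, camera adjusted p = 1.4e-06; adjusted p = 0.417 with an estimated correlation). Of 31 astrocyte genes Acsbg1 (2.37 ± 0.26) and Dio2 (at least 1.9-fold) rose over all genes and 16 when adjusted over the list alone (median 2.07, camera adjusted p = 2.31e-11; adjusted p = 0.417 with an estimated correlation). In all, 8 lists moved up and 9 down in NFIA cells by camera. Under the attached scanner files 4 of these were called in the other direction, astrocyte (camera adjusted p = 6.12e-05), oligodendrocyte lineage, neuronal and forebrain patterning genes, and 2 were kept, against 0 and 14 under the source names. Dnmt3b, a de novo DNA methyltransferase gene, fell by 2.52 ± 0.38, and Lin28a by 3.61 ± 0.65. The attached scanner files gave 0 called genes with 87 at an unadjusted p under 0.05, the 2 groups fitted alone gave 34, and leaving out any array of the 2 groups but PN_NFIA 2 gave 0. Leaving out PN_NFIA 2 gave 63, either PN_control array 0, and either SN_control array 709.

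**Figure D4:**
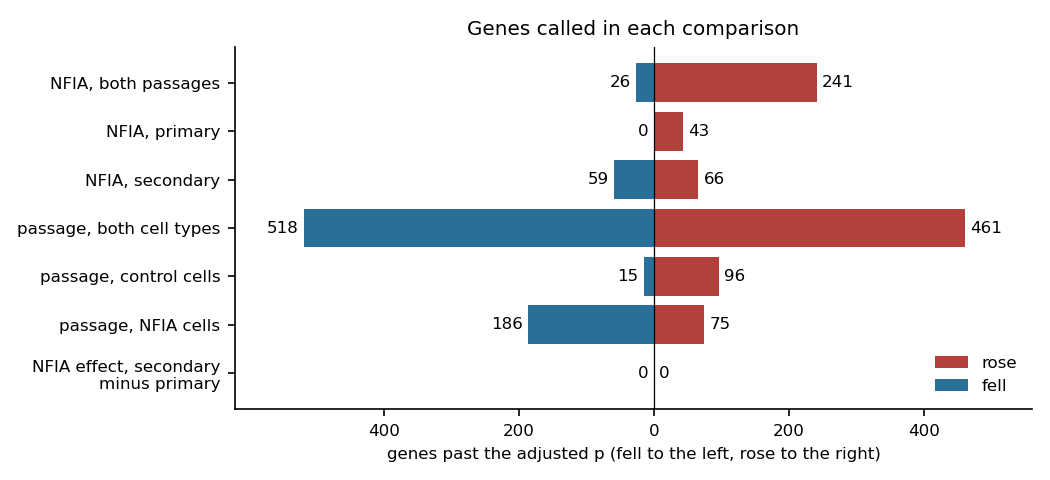
Genes past an adjusted p of 0.05 in limma in each of the 7 comparisons, with genes that rose to the right and genes that fell to the left of 0. The comparison between passages over both cell types has the most, 461 up and 518 down, and the difference of the NFIA effect between passages has 0.

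The last 2 comparisons set fold changes against each other across 13790 genes, which are not independent replicates. The NFIA effect in primary and in secondary neurospheres, which share no arrays, correlated with r = 0.414 (Spearman 0.344). This r was -0.0556 with arrays assigned as the scanner files are attached, and it was also lower under the source names. Of the 43 genes that rose in primary neurospheres 36 had the same sign in secondary ones, and 12 rose in both, Myh8 and Smad9 among them, against 0.21 for independent lists. The NFIA effect in primary neurospheres was then set against the passage effect in control cells, to ask whether NFIA moves cells the way passage does. These share the PN_control arrays, and correlated with r = 0.636 (Spearman 0.559) against 0.5 in simulated unchanged groups of independent arrays and 0.34 with arrays paired as measured. The covariance was 0.366 against 0.0987 and 0.0462 simulated, a difference of 0.268 and 0.32. Of the 43 genes that rose with NFIA 42 had the same sign with passage, and 29 rose in both, among them Tnc, Cyp1b1, Ccn4 and Col6a1, against 0.3 for independent lists. At these list sizes the simulated groups gave 41.2 of the same sign and 5.79 in both lists with independent arrays, and 37.3 and 2.92 with paired ones, so part of the excess may come from the shared controls. The comparison was not repeated with separate control arrays, since each part would hold 1 array.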

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

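The tests of the array assignment, of Y-linked genes and of epithelial genes were chosen after the results were seen, and those of scaling, of single arrays and of other splits before.

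The NFIA effect differed between passages for 9 gene lists by a test of the difference itself, although 0 single genes did in limma (919 at an unadjusted p under 0.05). Not all 9 calls held on leaving out PN_control 2, PN_NFIA 1 or any single secondary array, so the set depends on single arrays. Lower in secondary neurospheres were the effects on pluripotency (median difference -1.73, camera adjusted p = 4.92e-11), mesodermal (-1.64, 2.01e-09) and endoderm genes (-2.33, 1.49e-05). The same held for extracellular matrix genes (-1.50, 0.004), early progenitor genes (-1.02, 0.0145), neuronal genes (-0.74, 0.0169) and neural crest genes (-0.90, 0.0205). Higher were the effects on neural stem cell genes (0.31, 0.0174) and astrocyte genes (0.63, 0.04995), though the latter turned to lower without SN_control 1 (camera adjusted p = 0.857) and without the arrays of conflicting names (0.172). Calls turned to the other direction for 2 of the 9 lists under the attached scanner files, astrocyte (0.00258) and neuronal genes (0.0036). Under the source names they did for 8, with 6.27e-08 and 0.00274 for these 2, and 0 calls were kept under either. With an estimated correlation none passed, and the lowest adjusted p was 0.517.

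Pluripotency genes stood lower in SN_NFIA cells: 12 of 20 were lower in both SN_NFIA arrays than in both SN_control arrays, Pou5f1 at -3.72 and -2.67 against -1.27 and -0.22. The rest were not, among them Nanog at 0.04 and 0.29 against 0.54 and -0.27, and Sall4 at -1.06 and -0.9 against -1.63 and -1.5. For the median difference of effects array scaling is argued against, since it was -1.01 in the scaling that brought it closest to 0. A single array deciding that difference is argued against too. Its median was -1.20 without SN_control 2, the array whose removal brought it closest to 0. The difference also holds the opposite shift in primary neurospheres, so neither value tests the lower level in SN_NFIA cells by itself. A candidate explanation is a smaller share of undifferentiated or epithelial cells among SN_NFIA cells. Of 5 epithelial genes that such cells express, 5 were lower in both SN_NFIA arrays, Krt18 at -1.55 and -0.60 against 2.24 and 3.98. The 5 were chosen after the results were seen, and Krt8, Krt18 and Cdh1 among them are also members of the endoderm list. Cldn6 and Cdh1 had passed in secondary neurospheres and Krt18 in NFIA cells between passages, so the count is no independent support. Lower expression per cell also cannot be told apart from fewer cells in RNA of pooled cells.

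Of 6 Y-linked genes measured 3 stood lower in NFIA cells. Eif2s3y was at 2.83 and 3.03 in PN_control, 1.47 and -0.25 in PN_NFIA, 2.11 and 1.92 in SN_control, and -1.95 and -1.48 in SN_NFIA arrays. These 3, the ones above background in every control array (Ddx3y, Eif2s3y, Uty), were lower in each NFIA array, as loss of the chromosome from part of the NFIA cells may give. The other 3 moved the other way: Sly, at -2.87 and -0.25 in SN_NFIA, Ssty1, at -2.79 and -0.13, and Gm20736, at -2.99 and 0.1, were higher there than in every other array. Kdm5d, which was left out by the filter on dim probes, was at -0.81 in SN_NFIA 1 and -5.98 in SN_NFIA 2. In control arrays it lay between -6.6 and -5.4. In control arrays Sly and Gm20736 were above background once and Ssty1 never, so these genes cannot argue against loss. Loss cannot be told apart from changed expression. A share of control cells carried over in the sort may account for the intermediate level in PN_NFIA 1, where Ddx3y, Eif2s3y and Uty kept 45.5%, 36.4% and 51.4% of the control level. Only 27 genes there lay below the lower PN_control array by more than the distance of Eif2s3y from the mean of both (-1.46). When 1 control array was set against the other, 54 and 97 genes passed this threshold. The lower of 2 arrays is a stricter reference than a single one, so the counts are not alike and the test cannot tell.

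For 7 samples the value table and the attached scanner file hold different arrays. Among all ways to pair the 8 arrays, the groups of the value table ranked 1 by mean correlation within pairs (0.9699) and those of the attached files 102 (0.9362). The correlations were among the reasons for following the value table, so these ranks are no independent test of misattached files against misnamed columns. Slide positions use no expression values. By the value table, the samples in order took columns 1 to 4 of row 1, then columns 1 to 4 of row 2. The attached files gave no such order, with PN_control 1 at row 2, column 3. If arrays were loaded in sample order, this argues against misnamed columns. The order of loading was not tested.

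Other splits of the 8 arrays into sets of 4 were tested for both comparisons over all arrays. The real split called 267 genes for NFIA and 979 for passage, and each was the 1 of 34 splits with as many, the highest other giving 0. As equally numbered arrays of a passage are paired, the splits to set beside them are the 8 that part all 4 pairs, as NFIA does, and the 3 that part 0, as passage does. The highest other among these gave 0 too, and they are too few for a share under 0.05.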

How the results depend on the processing

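The file assignment, the replicate block within each passage, the crossed block and the inclusion of transcripts without a symbol were chosen after the results were seen.

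Of the 250 values of counts, correlations, lists called and Nfia under an alternative, 154 stayed within 1.5 times the count, on the same side of the test or within the spread. Averaging probes, the deposited value table, trend and robust variance, a fold of at least 2, the crossed block and transcripts without a symbol left every such value that they gave there. The deposited table holds the same scaled signals centred on each probe, so its agreement was given in advance. A fold of at least 2 could lower only the counts over all arrays, as genes called elsewhere changed by at least 1.29 (log2). No count past the test for the difference of effects arose except on leaving out an array.

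Without a filter on dim probes the counts were 143 (NFIA) and 452 (passage) over all arrays, 0 and 23 for NFIA in primary and secondary neurospheres and 52 and 71 for passage in control and NFIA cells, as more genes were tested. The correlations were then 0.485 with passage and 0.305 between passages. With only probes above background on all arrays, NFIA gave 15 in primary and 66 in secondary neurospheres, and passage in control cells 71. In primary neurospheres normexp gave 8, quantile normalization 19 and the percentile over probes above background on all arrays 65. The groups fitted alone gave 138, 0, 0 and 34 for NFIA in primary and secondary neurospheres and passage in control and NFIA cells, with fewer samples behind the spread. The replicate block gave 74 in secondary neurospheres. The replicate block within each passage gave 70 in primary and 644 in secondary neurospheres and took Nfia (1.00) past the test. Camera with an estimated correlation called 0% of the list tests. The cause was not tested for these unless given.

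Leaving out 1 array in turn, with a lone array assumed to vary like the other groups, gave 33 to 355 genes for NFIA over both passages, 51 to 1650 for passage over both cell types, 0 to 85 and 6 to 457 for NFIA in primary and secondary neurospheres, 8 to 434 and 0 to 709 for passage in control and NFIA cells, and 0 to 29 for the difference of effects. Nfia lay between 0.74 and 1.20, the correlations between 0.502 and 0.693 with passage and 0.239 and 0.480 between passages, and 41.4% to 50% of the list tests were called. Without the 2 arrays of conflicting names the counts were 67 for NFIA over both passages and 0 in the 5 others past the test, with fewer samples, and astrocyte genes pointed the other way in the difference of effects (camera adjusted p = 0.172). They also did without SN_control 1 (camera adjusted p = 0.857), in a range of 9.88e-05 to 0.986 over the arrays left out, and so did neuronal genes for passage in control cells without SN_control 2 (range 3.42e-06 to 0.98). Signal over background limits what can be measured, since between 45.4% and 56.4% of an array's spots were well above it.

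With arrays assigned as the scanner files are attached, 0 genes were called in every comparison, 16.2% of the list tests were called against 45.7%, the correlation with passage was 0.509 and that between passages -0.0556. The cause was not tested beyond the groupings above. For NFIA over both passages, genes with a reversed log2 difference were Myh8 -0.04, Rbp4 -0.83, Itga7 -0.11, Ddx3y 1.27, Eif2s3y 0.70, Uty 1.16, St18 0.51, Dll3 0.25, Hes1 -0.29, Cebpd -0.16, Prrx1 -0.01 and Klf4 -0.33. For NFIA over both passages, lists pointing the other way had a camera adjusted p of astrocyte 0.427, SOX9 and NFIA linked early glial 0.742, neuronal 0.0847, proneural and neurogenic progenitor 0.742, Notch pathway 0.664, cell cycle 0.664, early progenitor 0.0975, JAK-STAT and gp130 0.664, BMP and ID 0.454 and immediate early 0.664. For passage over both cell types, genes with a reversed log2 difference were Nfix -0.74, Nfia -0.47, Olig1 -1.02, S100a4 -0.30, Omg -1.28, Tbr1 0.62, Nhlh2 0.07, Gsx2 1.04, Nfib -0.37, Aldh1l1 -1.07, Slc1a3 -0.50, Sox8 -0.72, Mki67 0.06, Ccnd1 0.22, Slc17a6 0.37, Eomes 0.32, Pax6 0.34, Lin28b 0.21 and Dcn -0.55. For passage over both cell types, lists pointing the other way had a camera adjusted p of NFI family 0.437, astrocyte 0.297, SOX9 and NFIA linked early glial 0.753, neuronal 0.437, proneural and neurogenic progenitor 0.996, oligodendrocyte lineage 0.0624, pluripotency 0.8, mesoderm 0.996, forebrain patterning 0.8, cell cycle 0.437, early progenitor 0.912 and JAK-STAT and gp130 0.957. For NFIA in primary neurospheres, lists pointing the other way had a camera adjusted p of SOX9 and NFIA linked early glial 0.938, Notch pathway 0.0774, cell cycle 0.938 and JAK-STAT and gp130 0.938. For NFIA in secondary neurospheres, genes with a reversed log2 difference were Myh8 -0.32, Rbp4 -1.67, Scube2 -1.45, Mogat2 3.07, Ddx3y 1.76, Uty 1.77, Cldn6 2.66, Dsg1c 0.82, Acsbg1 -1.36, Id3 -1.48, Syt4 1.35, Neurod2 1.23, St18 0.86, Fgf4 1.95, Zscan10 2.02, Cdh1 1.81 and Mbp 0.80. For NFIA in secondary neurospheres, lists pointing the other way had a camera adjusted p of astrocyte 0.0097, SOX9 and NFIA linked early glial 0.803, neuronal 0.00477, proneural and neurogenic progenitor 0.136, pluripotency 0.0097, cell cycle 0.619, early progenitor 0.136, JAK-STAT and gp130 0.671, BMP and ID 0.247 and immediate early 0.176. For passage in control cells, genes with a reversed log2 difference were Cyp1b1 -0.05, Tbr1 0.10, Tnc -0.76, Nfix -0.60 and Pax6 0.10. For passage in control cells, lists pointing the other way had a camera adjusted p of NFI family 0.504, SOX9 and NFIA linked early glial 0.871, cell cycle 0.871 and extracellular matrix and adhesion 0.871. For passage in NFIA cells, genes with a reversed log2 difference were Krt18 0.41, Nhlh2 1.02, Cartpt 1.60, Mogat2 0.04, Grm5 -0.94, Esrrb 0.09, Utf1 0.25, Acsbg1 -0.24, Dnmt3b 0.32 and Lin28a 0.51. For passage in NFIA cells, lists pointing the other way had a camera adjusted p of NFI family 0.751, astrocyte 6.12e-05, SOX9 and NFIA linked early glial 0.536, neuronal 0.000348, proneural and neurogenic progenitor 0.0551, oligodendrocyte lineage 2.15e-06, endoderm 0.781, forebrain patterning 0.00367, cell cycle 0.408, early progenitor 0.458, JAK-STAT and gp130 0.751 and BMP and ID 0.536. For the difference of effects, lists pointing the other way had a camera adjusted p of astrocyte 0.00258, neuronal 0.0036, endoderm 0.766, early progenitor 0.51 and extracellular matrix and adhesion 0.51.

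With groups from the source names, 0 genes were called in every comparison, Nfia differed by -0.25, and the correlations were 0.177 with passage and 0.0818 between passages. Both arrays that these names call WT are titled NFIA, while all 4 arrays titled control count as NFIA. A difference by title is thus expected to turn in sign, and the reversals below are no independent evidence against it. Any further cause was not tested. For NFIA over both passages, genes with a reversed log2 difference were Ecrg4 -3.91, Myh8 -3.47, Wif1 -2.16, Rbp4 -3.17, Itga7 -2.95, Gas6 -2.11, Serpinb5 -2.72, Kcnt1 -2.10, Ddx3y 1.60, Eif2s3y 1.28, Uty 1.35, St18 1.84, Sparcl1 -1.58, Dll3 1.06, Hes1 -1.09, Cebpd -0.88, Smad9 -1.54, Rsad2 -1.69, Prrx1 -1.41, Acta2 -1.11 and Klf4 -1.16. For NFIA over both passages, lists pointing the other way had a camera adjusted p of NFI family 0.251, astrocyte 3.27e-09, SOX9 and NFIA linked early glial 0.133, neuronal 1.94e-06, proneural and neurogenic progenitor 6.03e-09, Notch pathway 0.548, mesoderm 0.119, cell cycle 0.0421, early progenitor 0.11, JAK-STAT and gp130 0.0127, BMP and ID 0.0449, interferon response 0.000468, immediate early 4.93e-11 and extracellular matrix and adhesion 0.00654. For NFIA in primary neurospheres, genes with a reversed log2 difference were Tnc -3.04, Hic1 -3.99, Cyp1b1 -3.71, Aldh3b1 -2.59, Myh8 -3.04, Col6a1 -2.12 and Cdkn2b -3.29. For NFIA in primary neurospheres, lists pointing the other way had a camera adjusted p of NFI family 0.428, astrocyte 0.603, SOX9 and NFIA linked early glial 0.603, neuronal 0.131, proneural and neurogenic progenitor 0.000172, Notch pathway 0.586, pluripotency 2.2e-07, endoderm 3.63e-06, mesoderm 6.37e-06, JAK-STAT and gp130 0.145, interferon response 2.76e-05, immediate early 3.75e-08 and extracellular matrix and adhesion 7.68e-09. For NFIA in secondary neurospheres, genes with a reversed log2 difference were Serpinb5 -3.48, Sftpc -3.54, Abca8a -2.93, Myh8 -3.89, Rbp4 -4.06, Scube2 -2.52, Mogat2 4.08, Ddx3y 3.06, Uty 2.62, Cldn6 2.42, Dsg1c 2.69, Acsbg1 -1.39, Id3 -1.51, Smad9 -1.66, Syt4 2.21, Neurod2 2.51, St18 2.41, Fgf4 1.35, Zscan10 1.47, Cdh1 1.67, Sox7 -2.54 and Mbp 1.42. For NFIA in secondary neurospheres, lists pointing the other way had a camera adjusted p of NFI family 0.536, astrocyte 2.75e-11, SOX9 and NFIA linked early glial 0.172, neuronal 1.48e-05, proneural and neurogenic progenitor 1.68e-05, Notch pathway 0.798, pluripotency 0.777, cell cycle 0.00282, early progenitor 0.00611, JAK-STAT and gp130 0.0815, BMP and ID 0.0518 and immediate early 4.03e-05. For the difference of effects, lists pointing the other way had a camera adjusted p of astrocyte 6.27e-08, neuronal 0.00274, neural stem cell and radial glia 0.169, pluripotency 0.00863, endoderm 0.00129, mesoderm 0.00693, neural crest and Schwann 0.00981, early progenitor 0.00274 and extracellular matrix and adhesion 0.00404.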

Other observations

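The facts about genes here were chosen after their values were seen. Some of these genes and lists were among those tested in the comparisons, but no separate test was run on the patterns described here.

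Posterior HOX genes separated the arrays by replicate. The list median was -1.81 and -4.78 in the PN_control arrays 1 and 2, -2.04 and -4.33 in PN_NFIA, -1.58 and -2.83 in SN_control and -0.03 and -2.96 in SN_NFIA, with the array numbered 1 higher in each of the 4 groups. Hoxc9, which patterns the thoracic spinal cord, stood at -0.16 and -4.99 in PN_control and at 1.02 and -1.65 in SN_NFIA. Forebrain patterning genes had medians of 0.38 and 1.60 in PN_control and 1.65 and -2.07 in SN_control.

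In both SN_control arrays several genes stood above their level in all other arrays. Dcstamp, a gene of cell fusion in osteoclasts, was at -2.12 and -1.75 there and at -6.71 and -6.55 in PN_control, and the receptor gene Ptgdr2 at -1.93 and -1.85 against -5.65 and -5.36. The olfactory receptor gene Olfr487 was at -2.61 and -1.44 against -6.29 and -6.06 in SN_NFIA. Xist lay between -6.67 and -5.18 in the 8 arrays.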
